A study of Rattus norvegicus with 6 samples.

How the data were processed

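The series measured messenger RNA levels by paired-end Illumina sequencing of TRIzol-extracted total RNA from primary ventricular cardiomyocytes of newborn Sprague-Dawley rats (postnatal day 1 to 3). The labels give 2 groups of 3 libraries: cells that received a negative-control small interfering RNA (siNC) and cells that received one against Mettl3 (siMettl3), each for 24 h before 6 h of lipopolysaccharide (LPS). All cells came from a single isolate pooled from several rats, so the p-values below measure the spread between these samples, which may be technical. No library without LPS was analysed here, so no value below is a response to LPS.

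The deposited table has 32623 genes with rat Ensembl identifiers, 1 column of values per library in each of 2 units. Per the file headers, the first unit is FPKM (fragments scaled to transcript length and library size), computed by the authors. Genes without reads carry 0.0001, which occurs exactly where the count is 0. Per the file headers, the second unit is counts, deposited by the authors as whole numbers without normalization. Within a gene the counts were proportional to FPKM: for 14527 genes with at least 20 counts in every library, 98.7% of values lay within 1% of a constant ratio. That would also arise if the counts had been derived from coverage, so the counts may not be raw reads. The processing notes name Bowtie 0.12.2 and the mouse build mm8 without a role, whereas the table lists rat genes and states no build, aligner, quantifier or annotation release. Coordinates are given as the table has them. The effective length of each gene was taken from the ratio of its counts to its FPKM.

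The total count per library was 71202469 to 76668751. At that depth counting error is small for most genes named, but not for LOC103689951 and Hiatl3, which had a count of 0 in some libraries. For the others the spread between libraries limits the precision. The chi-square per degree of freedom between replicates of a group was 22.1 to 63.1, where counting error alone would give about 1. The table lists 11351 genes with a count of 0 in all 6 libraries. A count of 0 was read as compatible with up to 3 counts in that library, for counting error only.

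Values were transformed as log2(FPKM + 1), and 13105 genes with a mean of at least 1 FPKM over the 6 libraries were tested. Of these, 12305 are protein-coding. The groups were compared, as siMettl3 minus siNC, with limma 3.58.1 (a linear model with moderated variances and an intensity trend, 2-sided) in R 4.3.3. The Benjamini-Hochberg threshold was 0.05. Log2 fold changes are on this scale and are therefore compressed for genes near 1 FPKM. The test had been fixed for a table of FPKM. Since the table also holds counts, edgeR 4.0.16 (quasi-likelihood, trimmed-mean normalization) and DESeq2 1.42.0 were run on them as alternatives fixed in advance for that case, and the edgeR results stand beside the main ones. Standard errors are limma's, and means are given with the SD of 3 libraries.

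Gene lists numbering 33 were fixed before the data were examined, for the m6A machinery, inflammation, cardiomyocyte function, metabolism, stress and the markers of other cell types. Of their 761 symbols, 726 were found and 678 tested. The 32 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists; camera asks whether a list moved against the other genes. The erythroid list had 3 tested members (Hba-a1, Hba-a2 and Hbb) and was left out. Calls were repeated with an estimated correlation, with camera on ranks and with fry, which asks whether a list's genes moved 1 way on balance without comparing them with other genes. With an estimated correlation camera uses only the residual degrees of freedom of the libraries, so it has less power than with the preset one. The number of members past the threshold is given over all genes tested and adjusted over the list alone. Where several genes share a symbol, the one with the highest mean stood for it.

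Gene Ontology and KEGG terms as the table annotates them were tested with a 2-sided Fisher exact test, for terms of 10 to 500 tested genes and separately for genes that rose and fell. The background was all tested genes with at least 1 term of that kind.

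The rule for naming genes was fixed before the data were examined: Mettl3, Mettl14 and Wtap; a panel of 8 inflammatory and cardiac genes whatever their values; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with at least 5 FPKM in the higher group and all libraries of one group above the other; and up to 4 members of each list with the smallest adjusted p. For the largest changes, identifiers that stand for an unnamed sequence clone or a numbered model of the rat database were not counted as gene symbols. That reading of the rule was set after the values had been seen. Where 5 or fewer members of a list rose or fell, those beyond the 4 were also named, as were a few further collagens, after their values had been seen. Results for some single genes that the rule would name were left out of the text.

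The tests were checked on simulated data made from these libraries. Of genes changed 1.5-fold, limma recovered 50% and edgeR 54%; at 2-fold they recovered 62% and 68%, and at 4-fold 96% and 100%. At 1.25-fold each recovered 6%. Of 12905 unchanged genes, limma called 6 and edgeR 8. A list of 25 genes lowered by 0.4 on the log2 scale was called, and 0 of 100 unchanged lists were. The simulated genes were drawn independently, whereas the estimated correlation within the fixed lists reached 0.885 (ribosomal proteins). The simulation therefore cannot show how often camera calls unchanged lists whose members move together.

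Alternatives fixed before the data were examined covered the pseudocount, the filter, the scaling, the variance model, the count tools, gene type, the threshold, each library left out in turn and the replicate number as a block. A correction for transcript length and a fit without replicate 2 of both groups were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.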

Results

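The data are 6 RNA-sequencing libraries of LPS-treated neonatal rat ventricular cardiomyocytes, 3 from cells with the control RNA (siNC) and 3 from cells with the RNA against Mettl3 (siMettl3). LPS is the bacterial endotoxin that Toll-like receptor 4 detects. The total count was 76668751, 74759017 and 71202469 in siNC replicates 1, 2 and 3 and 74026710, 74401683 and 72483469 in siMettl3 replicates 1, 2 and 3. Each library had counts for 18308 to 18667 genes, and the 10 most abundant genes took 13.6% to 15.4% of the counts. The mitochondrial chromosome took 11.9% to 13.1%. On the first principal component, which held 41.4% of the variance, the siNC libraries lay at -16.2, -21.7 and -7.57 and the siMettl3 libraries at 11.0, 26.5 and 8.03. The single comparison the design allows asks which genes differ between siMettl3 and siNC cells under LPS.

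Mettl3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on messenger RNA, was lower in the cells that received the RNA against it. Its level was 16.9 ± 1.47 FPKM in siNC and 10.3 ± 0.355 FPKM in siMettl3 (SD, n = 3), or 60.6% of the control. The log2 fold change was -0.67 (SE 0.0741, limma adjusted p = 0.00661), and edgeR gave -0.80 (adjusted p = 0.00293). The limma adjusted p was at most 0.0362 with 1 library left out. It was 0.0521 without replicate 2 of both groups, a fit chosen after seeing the data. With the replicate number as a block Mettl3 did not pass either. The table places the gene (ENSRNOG00000013111) on the minus strand of chromosome 15, from 28710300 to 28721127. Mettl14, the partner of Mettl3 in the catalytic core, measured 8.69 ± 1.29 and 9.38 ± 1.84 FPKM (adjusted p = 0.715), and Wtap, the adaptor of the complex, 21.0 ± 0.716 and 21.5 ± 1.03 FPKM (adjusted p = 0.748). Among the 23 tested genes of the m6A machinery, 4 rose and 1, Mettl3, fell, and the same held adjusted over the list alone. The members that rose were the insulin-like growth factor 2 mRNA-binding protein Igf2bp3 (0.41), the complex subunit Virma (0.35), the methyltransferase Mettl16 (0.32) and the RNA-binding protein Hnrnpc (0.25, log2 fold change each). The list as a whole did not pass (adjusted p = 0.0667). It did pass without siNC replicate 3 (0.0335), siMettl3 replicate 1 (0.0286) or siMettl3 replicate 3 (0.0486), and had adjusted p = 0.634 with an estimated correlation. By edgeR 0 of the 4 rises were called. By limma 0 of them were called without siNC replicate 1 or 2 or any 1 of the siMettl3 replicates, and without siNC replicate 3 only Igf2bp3 was (adjusted p = 0.0339).

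**Figure D1:**
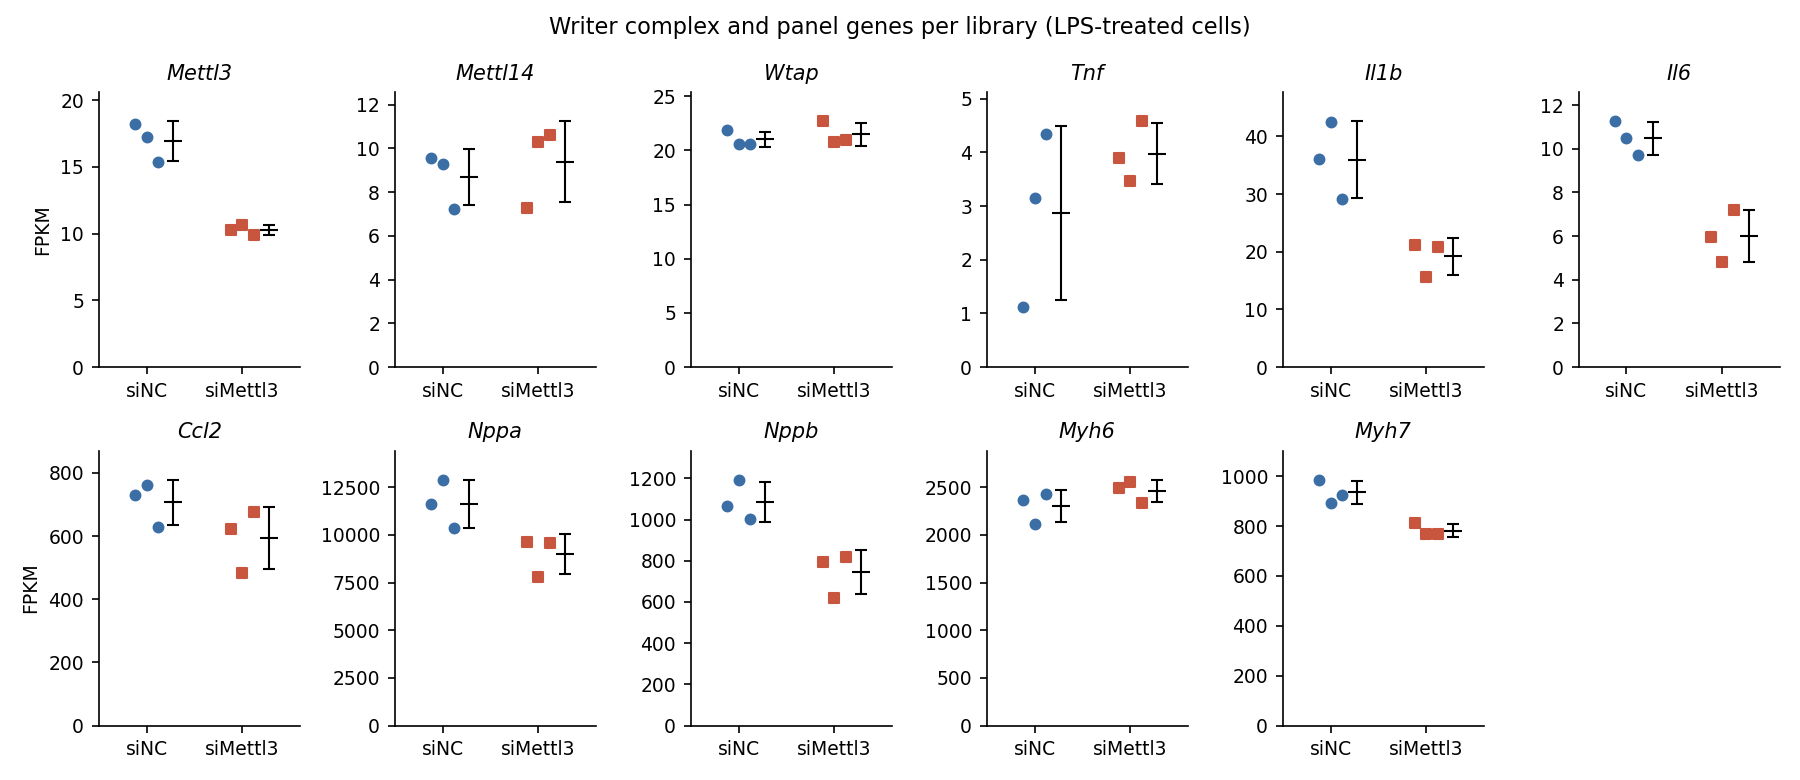
FPKM of Mettl3, Mettl14, Wtap and the 8 panel genes in each library (circles siNC, squares siMettl3, both under LPS), with the mean ± SD of 3 libraries as the bar beside them; every axis starts at 0. The siMettl3 libraries lie below all siNC libraries for Mettl3, Il1b, Il6, Nppa, Nppb and Myh7, of which Nppa (adjusted p = 0.181) and Myh7 (adjusted p = 0.0617) did not pass the threshold.

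The genes with the largest falls included an embryonic contractile gene and several genes of connective tissue. Myh3, the embryonic skeletal myosin heavy chain, went from 16.1 ± 2.0 to 1.03 ± 0.296 FPKM, a log2 fold change of -3.08. Cilp (-1.34), a matrix protein of cartilage, Grem1 (-1.28), a secreted antagonist of bone morphogenetic proteins, and Lox (-1.26), which cross-links collagen and elastin, fell as well. So did Crabp1 (-1.29), a retinoic acid-binding protein, and Ca3 (-1.25), a carbonic anhydrase. The remaining falls of the 10 largest were Hiatl3 (-2.89), LOC102553715 (-1.31), LOC103689942 (-1.22) and Ceacam4 (-1.21), the last pair close in level (10.2 ± 1.03 and 9.35 ± 1.02 FPKM in siNC). The largest rises among well annotated genes were Stx7 (1.45), a syntaxin of endosomes, and Reg3b, a secreted lectin of the acute-phase response, which went from 95.2 ± 10.8 to 260 ± 18.8 FPKM (1.44). The related arrestin-domain genes Arrdc4 (8.30 ± 0.396 to 20.5 ± 2.004 FPKM, 1.20) and Txnip (158 ± 10.5 to 299 ± 13.6 FPKM, 0.92), both known targets of the glucose-sensing transcription factor MondoA, rose together. So did Lifr (1.02), the receptor for leukaemia inhibitory factor, Adgrg1 (0.99), an adhesion G protein-coupled receptor, Elf2 (0.95), an ETS-family transcription factor, Map1b (0.92), a microtubule-associated protein, and the unnamed LOC103690354 (1.52).

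Each of those 20 genes, with LOC103689951 as the remaining rise, was also called by edgeR, and by construction of the naming rule its libraries separated by group. LOC103689951 had a count of 0 in all siNC libraries and 485, 543 and 177 in the siMettl3 libraries. Against 3 counts in each siNC library it was at least 134-fold higher, though 87 tested genes had a count of 0 in a library and at least 100 in another of the same group. Hiatl3 had 82 counts in siMettl3 replicate 2 and 0 in the other siMettl3 libraries, and DESeq2 did not call it (adjusted p = 0.0832). LOC102553715 overlaps LOC100912585 on the opposite strand. When 1 library was left out, 17 of the 20 stayed past the threshold in every case. LOC102553715 was lost without siNC replicate 1 (adjusted p = 0.0743), siMettl3 replicate 1 (0.0686) and siMettl3 replicate 2 (0.0514). Lifr reached 0.114 without siNC replicate 1, 0.0861 without siNC replicate 2, 0.0876 without siMettl3 replicate 1, 0.0913 without siMettl3 replicate 2 and 0.0753 without siMettl3 replicate 3, and Map1b reached 0.102, 0.0788, 0.0781, 0.0686 and 0.0613 in the same order.

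**Figure D2:**
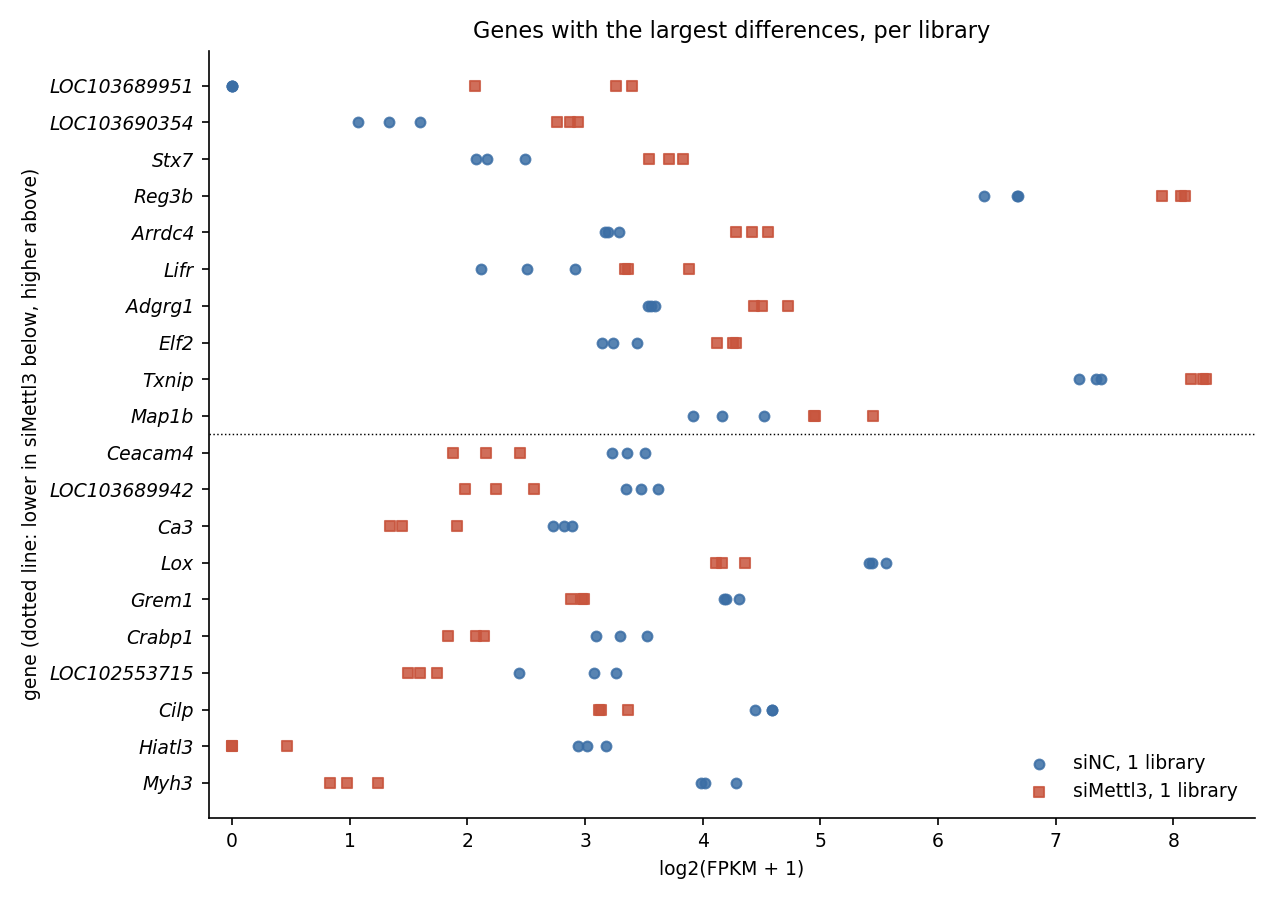
Log2(FPKM + 1) of the 10 genes with the largest rise (above the dotted line) and the 10 with the largest fall (below it), 1 point per library (circles siNC, squares siMettl3). For each gene the 3 libraries of one group lie to one side of the other 3, with Myh3 at 16.1 FPKM in siNC and 1.03 FPKM in siMettl3 on average.

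Across all 13105 tested genes, 1432 passed the threshold, 856 higher and 576 lower in siMettl3, and 12 of the higher and 29 of the lower genes changed at least 2-fold (log2 of at least 1). The libraries of all 1432 separated by group, as did those of 37.9% of tested genes. For a single gene chance gives 10%. Genes move together, so the share in 1 division of the libraries can lie far from that by chance. It was not computed for the other divisions. Whether more genes rose or fell depended on the test, the scaling and the libraries. By edgeR 444 genes were higher and 864 lower, of 1308. By DESeq2 the numbers were 1010 and 1384, of 2394. They were 358 and 781 after median-ratio scaling of FPKM, 469 and 752 after quantile normalization, and 698 and 1211 after the length correction. The median log2 fold change of all genes was 0.067 as deposited and 0.0058 after median-ratio scaling. limma and edgeR shared 997 genes, 435 higher and 562 lower, with the same sign in all 997. The count was lower whichever library was left out, which lowers the power by construction. It was 224 (93 higher), 402 (183) and 861 (471) without siNC replicates 1, 2 and 3, and 206 (83), 451 (198) and 550 (224) without siMettl3 replicates 1, 2 and 3. More genes thus fell than rose in all but the fit without siNC replicate 3, as they did at an adjusted p under 0.01 (69 higher, 110 lower). Of these genes 214, 383, 748, 199, 438 and 511 were among the 1432, in that order. With the replicate number as a block the count was 6 (1 higher, 5 lower).

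**Figure D3:**
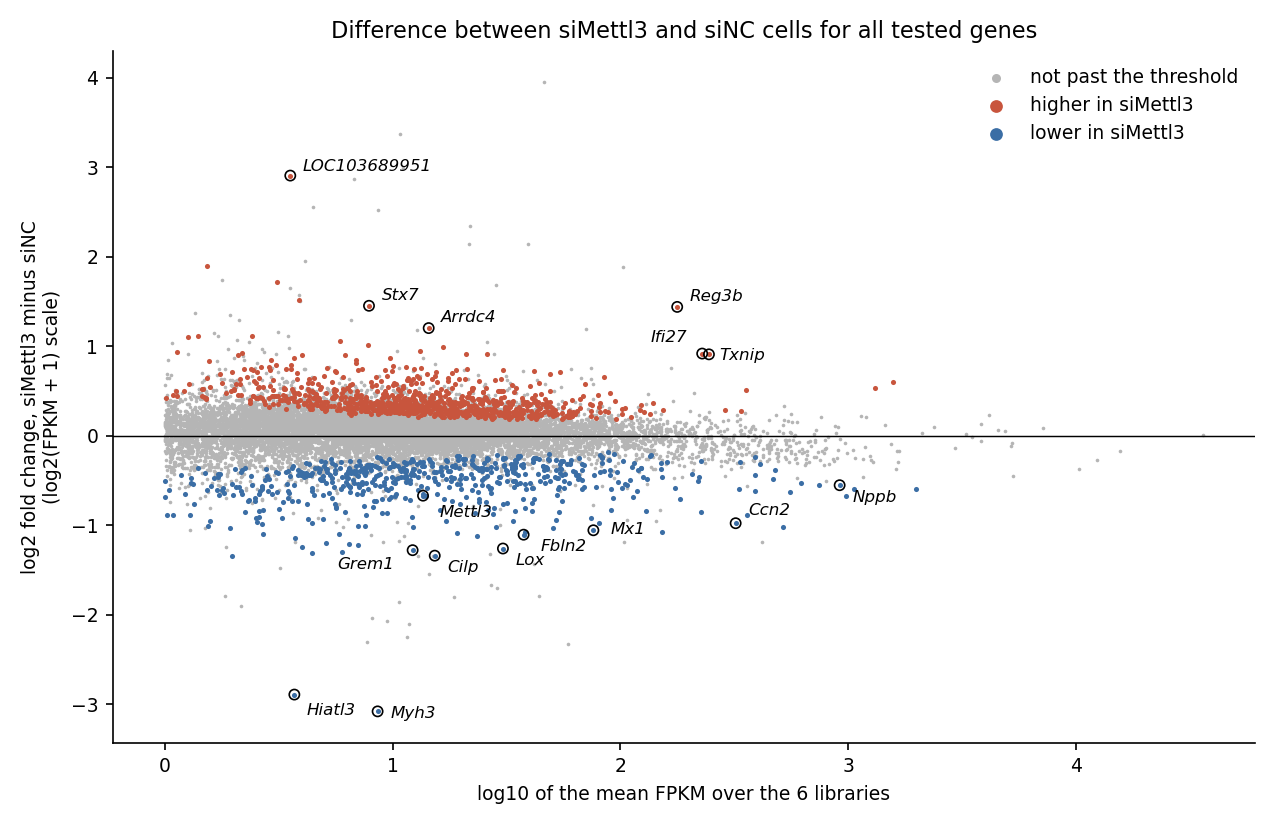
Log2 fold change (siMettl3 minus siNC, on log2(FPKM + 1)) against the log10 of the mean FPKM for the 13105 tested genes, 1 point per gene, red for the 856 that rose, blue for the 576 that fell and grey for the others; circled genes are named. Most called genes lie within 1 log2 unit of 0, and Myh3 has the largest called fall at -3.08; after the alternative scalings more genes fell than rose.

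Genes of the extracellular matrix and of the response to transforming growth factor beta fell together. Of 30 tested members 20 fell and 0 rose, 25 and 0 adjusted over the list alone, and all 30 had a fold change below 0. Ccn2, the matricellular connective tissue growth factor, went from 425 ± 25.05 to 216 ± 18.6 FPKM (-0.98). Thbs1 (thrombospondin 1, -0.89) and Lox (-1.26) were also among the members with the smallest p, and the collagens Col3a1 (-0.84), Col5a2 (-0.68) and Col1a1 (-0.67, 1196 ± 17.6 to 752 ± 30.2 FPKM) fell too. The markers of fibroblasts moved with them: 7 of 14 fell and 0 rose (12 and 0 adjusted over the list alone), among them the matrix glycoprotein Fbln2 (51.6 ± 1.15 to 23.5 ± 1.89 FPKM, -1.10) and Islr (-0.73). Col1a1 and Col3a1 belong to both lists. The camera test gave adjusted p = 1.55e-24 for the matrix list and 4.82e-10 for the fibroblast markers, and adjusted p = 0.197 and adjusted p = 0.279 with an estimated correlation. By edgeR 25 matrix genes and 9 fibroblast markers fell.

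Of the 32 lists tested, 13 passed with the preset correlation, 11 lower and 2 higher, 11 lists passed by fry and 0 with an estimated correlation, where the smallest adjusted p was 0.197. That run has less power by construction. For the cholesterol list the estimated correlation was -0.022, below the preset 0.01, yet its unadjusted camera p went from 1.46e-04 to 0.0137. Not passing it therefore does not show that correlation between genes made a call. Other divisions of the 6 libraries into 3 and 3 called up to 13 lists, and 0 list members in each of them. Those divisions mix the groups unequally and keep part of any group difference, so a real shift could be called there too. Without siNC replicates 1, 2 and 3 and siMettl3 replicates 1, 2 and 3, the matrix genes that fell numbered 12, 15, 16, 12, 14 and 14, and the fibroblast markers 3, 3, 3, 3, 3 and 5. Islr was called without siMettl3 replicate 3 and lost in the other fits, with adjusted p of 0.112, 0.0922, 0.0535, 0.101 and 0.0886 in that order.

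**Figure D4:**
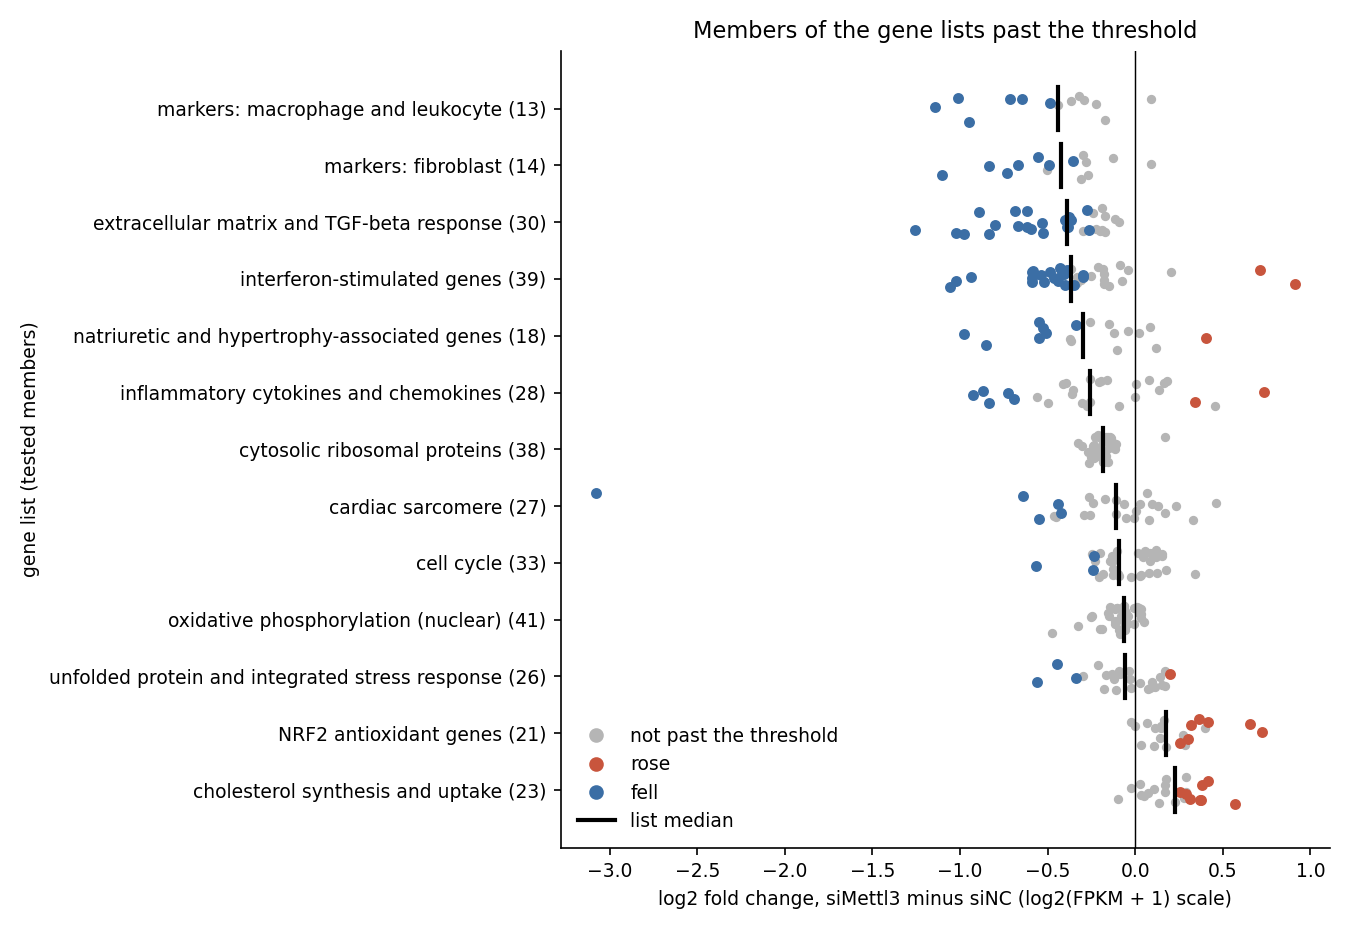
Log2 fold change (siMettl3 minus siNC) of the tested members of the 13 lists past the threshold, 1 point per gene with jitter along the vertical axis, red where the gene rose, blue where it fell, grey where it did not pass; the black bar is the list median and the number in brackets the tested members. The macrophage, fibroblast and matrix lists have the lowest medians (-0.44, -0.43 and -0.39) and the NRF2 and cholesterol lists medians of 0.17 and 0.23; 0 of the 13 lists passed with an estimated correlation.

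Interferon-stimulated genes, the antiviral programme induced by interferon, were mostly lower in siMettl3 cells. Of 39 tested members 21 fell and 2 rose (27 and 3 adjusted over the list alone). The antiviral GTPase Mx1 went from 103 ± 3.08 to 49.3 ± 7.60 FPKM (-1.05), Ifit2 from 68.2 ± 4.62 to 33.1 ± 4.21 FPKM (-1.03), and the nucleotide kinase Cmpk2 fell by 0.94 on the log2 scale. The 2 members that rose were Ifi27 (170 ± 25.7 to 319 ± 23.1 FPKM, 0.91) and the virion-tethering protein Bst2 (41.2 ± 7.54 to 67.6 ± 5.94 FPKM, 0.71). Among 28 inflammatory cytokines and chemokines 5 fell and 2 rose (12 and 2 adjusted over the list alone). Il33, an alarmin, fell by 0.69 and the chemokine Ccl3 by 0.83 on the log2 scale, as did the chemokine Ccl12 by 0.93, while the chemokines Cx3cl1 (fractalkine, 0.34) and Ccl5 (0.73) rose. The interleukins Il1b (35.9 ± 6.66 to 19.2 ± 3.15 FPKM, -0.87) and Il6 (10.5 ± 0.760 to 6.00 ± 1.19 FPKM, -0.73) fell. Tnf, at 2.87 ± 1.62 and 3.98 ± 0.563 FPKM (0.46, adjusted p = 0.359), and Ccl2, at 707 ± 70.8 and 595 ± 99.2 FPKM (-0.26, adjusted p = 0.249), did not pass. Markers of macrophages and leukocytes moved the same way as these genes: 6 of 13 fell and 0 rose (8 and 0 adjusted over the list alone), among them the complement component C1qa (5.54 ± 1.35 to 1.93 ± 0.318 FPKM, -1.14), C1qb (-1.01) and lysozyme Lyz2 (44.4 ± 3.49 to 22.8 ± 4.47 FPKM, -0.95). The labels give no count of cell types. A lower share of macrophages in the siMettl3 cultures therefore cannot be told apart from a lower level of the inflammatory genes within cells, and neither was tested.

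The adjusted p was 4.48e-16 for the interferon list, 3.65e-05 for the cytokines and 4.89e-08 for the macrophage markers, against adjusted p = 0.383, 0.629 and 0.197 with an estimated correlation. By edgeR 24, 9 and 8 of their members fell. These lists were also called in 6, 5 and 6 of the other divisions of the libraries. Their mean differences from other genes were -0.38, -0.28 and -0.56. In the other divisions they were at most 0.24, 0.23 and 0.28 in size. With siNC replicates 1, 2 and 3 and siMettl3 replicates 1, 2 and 3 left out in turn, the interferon-stimulated genes that fell numbered 3, 9, 11, 3, 8 and 21, newly called ones included. The cytokines that fell numbered 2, 2, 4, 0, 3 and 7 on the same terms, and the macrophage markers 1, 4, 6, 1, 3 and 4. Il1b passed only without siNC replicate 3, with adjusted p of 0.0890, 0.0650, 0.0692, 0.0573 and 0.0538 without siNC replicates 1 and 2 and siMettl3 replicates 1, 2 and 3. Il6 was lost without siNC replicate 1 (0.0856), siNC replicate 2 (0.0650) and siMettl3 replicate 1 (0.0774). Ccl3 (0.0533), Il33 (0.0519) and Ifi27 (0.0518) were lost without siMettl3 replicate 1. Cx3cl1 passed only without siNC replicate 3, with 0.0838, 0.0610, 0.0630, 0.0534 and 0.0596 in the order given for Il1b. Ccl5 passed only without siMettl3 replicate 2, with 0.0809, 0.0801, 0.0627, 0.0918 and 0.0595 without siNC replicates 1, 2 and 3 and siMettl3 replicates 1 and 3, and Ccl12 only without siMettl3 replicate 3 (0.114, 0.132, 0.0775, 0.135 and 0.126 in the other fits). Bst2 was lost without siNC replicate 1 (0.0757) and siMettl3 replicates 1, 2 and 3 (0.0889, 0.0561 and 0.0754). C1qa and Lyz2 were lost without siNC replicate 1 (0.0564 and 0.0617) and siMettl3 replicate 1 (0.0555 and 0.0598).

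Several genes of the contractile apparatus and of the hypertrophic response were lower. Of 27 tested sarcomere genes 5 fell and 0 rose (9 and 0 adjusted over the list alone): Myh3, the M-band protein Myom2 (33.2 ± 2.32 to 21.0 ± 0.914 FPKM, -0.64), skeletal alpha-actin Acta1 (-0.55), Xirp1 (-0.44) and Myoz2 (-0.42). The main myosins of the heart did not pass: Myh6 measured 2303 ± 166 and 2459 ± 117 FPKM (adjusted p = 0.532) and Myh7 934 ± 46.3 and 782 ± 25.4 FPKM (adjusted p = 0.0617), although edgeR called Myh7 lower (-0.33, adjusted p = 0.0205). Among 18 natriuretic and hypertrophy-associated genes 7 fell and 1 rose (9 and 1 adjusted over the list alone). Nppb, which encodes B-type natriuretic peptide, went from 1086 ± 96.2 to 745 ± 107 FPKM (-0.55), endothelin 1 (Edn1) fell by 0.52 and the actin-binding Cnn1 by 0.85 on the log2 scale, while the stress cytokine Gdf15 rose (0.41). Nppa, at 11628 ± 1249 and 9005 ± 1038 FPKM (-0.37, adjusted p = 0.181), did not pass. Smooth muscle and pericyte markers moved with these in part: Cnn1, Acta2 (2386 ± 115 to 1576 ± 59.1 FPKM, -0.60), Tagln (-0.59) and Myh11 (-0.46), all of the contractile apparatus, fell. That made 4 of 12 with 0 rises (4 and 2 adjusted over the list alone). The list did not pass (adjusted p = 0.166), though camera on the edgeR statistics called it (adjusted p = 0.00384). Of 26 genes of calcium handling and ion channels 4 rose and 0 fell (7 and 1 adjusted over the list alone), among them the pacemaker channel Hcn4 (8.93 ± 0.385 to 15.8 ± 1.82 FPKM, 0.75), the connexin Gja5 (0.50) and the calcium channel Cacna1h (0.32), with adjusted p = 0.186 for the list.

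The adjusted p was 8.89e-05 for the sarcomere list and 3.57e-06 for the hypertrophy list, and adjusted p = 0.279 and adjusted p = 0.338 with an estimated correlation; quantile normalization ended the sarcomere call (adjusted p = 0.133), and edgeR called 9 members of either list lower. Without siNC replicates 1, 2 and 3 and siMettl3 replicates 1, 2 and 3, the sarcomere genes that fell numbered 2, 3, 5, 2, 4 and 3 and the hypertrophy genes 3, 4, 5, 3, 4 and 4. The smooth muscle markers that fell numbered 1, 3, 4, 1, 3 and 2, and the channel genes that rose 2, 2, 2, 1, 2 and 3. Nppb was lost in each of these fits, with adjusted p of 0.115, 0.112, 0.0580, 0.0932, 0.0647 and 0.0642 in that order. Gdf15 was lost without siNC replicates 1 and 2 (0.0501 and 0.0650) and siMettl3 replicates 1 and 3 (0.0774 and 0.0594). Gja5 was lost without siMettl3 replicate 1 (0.0528). Cacna1h passed only without siMettl3 replicate 3, with 0.123, 0.114, 0.0761, 0.117 and 0.0893 in the other fits, and edgeR did not call it (adjusted p = 0.0560).

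Antioxidant and cholesterol genes were the lists that rose with the preset correlation, and neither passed with an estimated one (adjusted p = 0.322 and adjusted p = 0.197). Of 21 targets of NRF2, the transcription factor of the antioxidant response, 7 rose and 0 fell (10 and 0 adjusted over the list alone): haem oxygenase Hmox1 (31.3 ± 1.45 to 52.4 ± 3.31 FPKM, 0.72), Osgin1 (0.66), catalase Cat (0.42), the autophagy receptor Sqstm1 (0.36), thioredoxin reductase Txnrd1 (0.32), Tkt (0.30) and Gclm (0.25). Of 23 genes of cholesterol synthesis and uptake 8 rose and 0 fell (9 and 0 adjusted over the list alone), including the synthesis enzymes Dhcr7 (7.92 ± 0.637 to 12.2 ± 0.998 FPKM, 0.57) and Fdft1 (0.38). In the ferroptosis and glutathione list 6 of 21 rose and 2 fell (10 and 4 adjusted over the list alone; list adjusted p = 0.368). Hmox1, Nfe2l2 (0.25), which encodes NRF2 itself, and 4 others rose, and the glutathione-degrading Chac1 (-0.56) and the prostaglandin synthase Ptgs2 (-0.52) fell. Of 25 fatty acid oxidation genes 4 rose and 1 fell (5 and 5 adjusted over the list alone; list adjusted p = 0.539), with the carnitine palmitoyltransferases Cpt1a (18.3 ± 0.602 to 26.5 ± 2.49 FPKM, 0.51) and Cpt2 (0.35), Acsl1 (0.26) and Hadh (0.22) higher and the thioesterase Acot2 (-0.46) lower. Of 21 glycolysis genes the glucose transporter Slc2a1 rose (35.3 ± 1.78 to 48.9 ± 1.34 FPKM, 0.46), and the insulin-responsive transporter Slc2a4 (-0.50) and muscle phosphoglycerate mutase Pgam2 (-0.47) fell (2 rose and 4 fell adjusted over the list alone; list adjusted p = 0.123).

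The adjusted p was 1.85e-04 for the NRF2 list and 4.67e-04 for the cholesterol list with the preset correlation. By edgeR 5 NRF2 and 6 cholesterol genes rose, in the ferroptosis list 1 rose and 4 fell, and in the fatty acid oxidation list 2 rose (Cpt1a and Cpt2) and 5 fell. Without siNC replicates 1, 2 and 3 and siMettl3 replicates 1, 2 and 3, the NRF2 genes that rose numbered 2, 5, 5, 2, 4 and 5, newly called ones included. The cholesterol genes numbered 1, 3, 6, 0, 4 and 3 in the same order. The ferroptosis genes that rose numbered 1, 2, 2, 1, 2 and 1, and the fatty acid oxidation genes 0, 2, 2, 0, 2 and 2. Acsl1 (0.0964, 0.0817, 0.0570, 0.0934, 0.0675 and 0.0521 in that order) and Hadh (0.116, 0.116, 0.0660, 0.118, 0.0641 and 0.105) were lost in every fit. Tkt was lost in every fit too. Osgin1 passed only without siMettl3 replicate 3 (adjusted p = 0.0209) and Gclm only without siNC replicate 3 (0.0487). Slc2a4 was lost without siNC replicate 2 (adjusted p = 0.0523) and siMettl3 replicate 1 (0.0631), and Pgam2 without siNC replicate 2 (0.0505), siMettl3 replicate 1 (0.0686) and siMettl3 replicate 3 (0.0504); Slc2a1 was kept in all 6 fits.

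Small shifts of many members carried the lists of cytosolic ribosomal proteins and of nuclear oxidative phosphorylation genes. Of 38 ribosomal protein genes 37 had a fold change below 0, with a median of -0.18, and of 41 oxidative phosphorylation genes 34 did, with a median of -0.066. However, 0 members of either list passed the gene threshold, over all genes or adjusted over the list alone; by edgeR 1 oxidative phosphorylation gene fell. Their transcripts are short, with median lengths of 792 and 1044 bp against 2297 bp over all tested genes, and the log2 fold change rose with length (Spearman correlation 0.246). After the length correction 4 ribosomal protein and 2 oxidative phosphorylation genes fell, and camera gave the lists adjusted p = 3.70e-07 and 0.00462. Without that correction the lists passed at adjusted p = 2.38e-08 and 5.08e-04, and had adjusted p = 0.634 and adjusted p = 0.684 with an estimated correlation. Without siMettl3 replicate 2 the ribosomal median was -0.073, and the oxidative phosphorylation list was lost (mean difference from other genes -0.058, from -0.14). The oxidative phosphorylation list was also lost after quantile normalization. Of the 13 genes encoded by the mitochondrial genome 0 rose and 0 fell (0 and 0 adjusted over the list alone; list adjusted p = 0.386). Of 33 cell cycle genes 3 fell (also 3 adjusted over the list alone): the replication clamp Pcna (93.0 ± 8.22 to 62.4 ± 4.17 FPKM, -0.57), the helicase subunit Mcm6 (-0.24) and the ribonucleotide reductase subunit Rrm2 (-0.24), with list adjusted p = 0.00900, and adjusted p = 0.328 with an estimated correlation. In the unfolded protein and integrated stress response list 3 of 26 fell and 1 rose (4 and 1 adjusted over the list alone), with Chac1 (-0.56), Vldlr (-0.45) and Atf3 (-0.34), genes of the integrated stress response, lower and the chaperone Hyou1 (0.20) higher. That list passed at adjusted p = 0.0321, had adjusted p = 0.634 with an estimated correlation, and was lost without siMettl3 replicate 2 (mean difference -0.085, from -0.12). Quantile normalization ended its call too. Without siNC replicates 1, 2 and 3 and siMettl3 replicates 1, 2 and 3, the cell cycle genes that fell numbered 0, 1, 2, 0, 1 and 1, and the stress response genes 0, 1, 2, 0, 2 and 3. These counts include newly called genes. Mcm6, Rrm2 and Atf3 were lost in each of these fits, with limma adjusted p of at least 0.0527, 0.0545 and 0.0607. Hyou1 was lost in each of them too (0.115, 0.125, 0.0676, 0.125, 0.0948 and 0.103) and by edgeR (adjusted p = 0.141).

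The remaining lists did not pass. Of 29 genes of Toll-like receptor 4 and NF-kB signalling, the LPS co-receptor Cd14 (-0.53) and Tlr2 (-0.35) fell and the NF-kB cofactor Bcl3 (0.42) rose (2 and 2 adjusted over the list alone; list adjusted p = 0.183, and 0.0454 without siNC replicate 2). Among 18 adhesion and acute-phase genes Ptgs2 (-0.52) and the leukocyte adhesion molecule Icam1 (-0.38) fell, and the metalloreductase Steap4 (0.54) and E-selectin Sele (0.42) rose (2 and 2; 0.374). Of 12 inflammasome genes Casp4 (-0.71), the caspase that binds intracellular LPS, and Il1b fell and Txnip rose (3 fell and 1 rose; 0.128). Of 23 immediate early genes the phosphatase Dusp1 (23.0 ± 1.20 to 13.5 ± 1.34 FPKM, -0.73) and Atf3 fell, and the transcription factors Egr1 (26.8 ± 1.37 to 40.3 ± 2.74 FPKM, 0.57) and Jund (0.27) rose (3 and 4; 0.224). Of 16 genes of RNA interference and sensing of double-stranded RNA the sensors Ddx58 (-0.54), Ifih1 (-0.52) and Eif2ak2 (-0.49), which are also interferon-stimulated, fell and Mavs (0.28), the adaptor of Ddx58 and Ifih1, rose (4 and 3; 0.564). The apoptosis list of 26 had the pro-apoptotic Bmf (0.54) and Bcl2l11 (0.36) higher and the caspase Casp12 (-0.48) among the lower (2 fell and 6 rose; 0.901). Of 22 p53 targets Sesn1 (0.35) rose and Ccng1 (-0.30) fell (2 and 2; 0.868), of 16 heat shock genes Bag3 (0.26) rose (0 fell and 1 rose; 0.534), and of 26 autophagy genes Sqstm1 rose (0 fell and 1 rose; 0.976). In each pair of brackets the counts are the members that fell and rose adjusted over the list alone, and the last value is the list's adjusted p. Markers of the other cell types did not move as lists. Of 8 endothelial markers the cadherin Cdh5 (0.51) and the receptor Tek (0.36) rose and Egfl7 (-0.45) fell (1 fell and 2 rose adjusted over the list alone; list adjusted p = 0.313). Of 8 epicardial and mesothelial markers Lrrn4 (0.87) rose and mesothelin Msln (-0.88) and keratin Krt18 (-0.48) fell (3 fell and 2 rose adjusted over the list alone; list adjusted p = 0.480). Of 5 markers of Schwann cells and neurons 0 passed (0 fell and 1 rose adjusted over the list alone; list adjusted p = 0.976). Over all lists that did not pass, 60 members were called, 43 of them also by edgeR. Among those edgeR did not call were the rises of Mavs, Bcl2l11 and Bag3, which were also lost after median-ratio scaling and after quantile normalization. Without siNC replicates 1, 2 and 3 and siMettl3 replicates 1, 2 and 3, 15, 23, 38, 13, 27 and 33 of the 60 stayed past the threshold, and 12 did in all 6 fits. Of the markers named here, Lrrn4 and Msln were kept in all 6, whereas Tek and Egfl7 were kept in 0, Krt18 in 1 and Cdh5 in 2.

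Annotation terms of matrix and antiviral defence were enriched among the genes that fell. Of 140 genes annotated with the extracellular matrix 42 fell, against 6.40 by chance (Fisher exact test, adjusted p = 5.57e-20), and of 101 genes of defence against viruses 22 fell (adjusted p = 2.37e-07). In all, 119 Gene Ontology and 15 KEGG terms were enriched among genes that fell. Fatty acid metabolic process was the leading term among genes that rose, with 20 of 95 against 6.47 by chance (exact adjusted p = 0.00358), 1 of 2 Gene Ontology and 3 KEGG terms on that side. With genes that changed at least 2-fold, 3 terms were enriched, against 139 in all with the 1432 called genes. Genes are not independent samples, so these p-values describe the lists of called genes. The enrichment was not corrected for transcript length, with which the log2 fold change rose (Spearman correlation 0.246).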

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

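The length correction and the fit without replicate 2 of both groups were chosen after the data were seen; the other alternatives were fixed before. Mettl3 stayed lower with an adjusted p under the threshold in all settings but 2 (1.63e-14 to 0.0726 over all), and its log2 fold change was -0.73 to -0.62 when 1 library was left out. The list direction is that of camera's test on moderated statistics, so for a list near 0 it can differ in sign from the mean difference from other genes, the value given here. Of 143 called members of all lists, 33 stayed past the threshold with each library left out in turn and edgeR called 121. The robust variance model gives no list value, as camera has no such option. Depth is not the limit for most genes named, LOC103689951 and Hiatl3 excepted: between replicates the chi-square per degree of freedom was 22.1 to 63.1. Where a value below differs from the report, the cause was not tested, except that leaving out libraries lowers the power by construction.

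The count was 206 to 861 with 1 library left out (83 to 471 higher, 123 to 390 lower) and 192 without replicate 2 of both groups (77 higher, 115 lower), where Mettl3 had a log2 fold change of -0.68 and adjusted p = 0.0521. The replicate number as a block gave 6 genes (1 higher, 5 lower) and left Mettl3 at -0.67 with adjusted p = 0.0726. Correlations of the deviations of libraries with the same number were 0.035, -0.25 and -0.12. They show no deviation shared by number, but cannot establish that the samples were not handled in pairs. An adjusted p under 0.01 gave 179 genes (69 higher, 110 lower), no filter 903 (500 higher), DESeq2 2394 (1384 lower), and the length correction 1211 lower. The higher genes numbered 358 after median-ratio scaling, 469 after quantile normalization and 444 by edgeR. With genes changed at least 2-fold, 3 terms were enriched.

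Of the genes named that did not pass, 3 changed sign. Wtap was -0.038 after median-ratio scaling, -0.018 after quantile normalization, -0.043 by edgeR and -0.039 by DESeq2, -0.053 after the length correction, and -0.0076 to 0.057 with 1 library left out. Myh6 was -0.055 after the length correction, and Mettl14 -0.022 to 0.25 with 1 library left out.

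With an estimated correlation 0 lists passed. The mean differences are those of the main test: cytokines -0.28, interferon-stimulated genes -0.38, sarcomere -0.27, hypertrophy -0.33, oxidative phosphorylation -0.14, cholesterol 0.16, NRF2 0.19, stress response -0.12, cell cycle -0.10, ribosomal proteins -0.24, matrix -0.53, fibroblast -0.51 and macrophage -0.56. By fry, whose value is the mean log2 fold change, the cytokines (-0.22), oxidative phosphorylation (-0.090), the stress response (-0.065), the cell cycle (-0.048) and ribosomal proteins (-0.18) did not pass, whereas p53 targets (0.080), ferroptosis (0.081) and smooth muscle markers (-0.11) did. Fry's direction was opposite to camera's for fatty acid oxidation (0.00083), apoptosis (0.051), heat shock (-0.017), RNA sensors (0.0049), endothelial (-0.071) and Schwann cell markers (0.074), none of which passed.

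Scaling and filters ended or made a few list calls. After quantile normalization the sarcomere (-0.16), oxidative phosphorylation (-0.029) and stress response (-0.076) lists did not pass, and the uncalled mitochondrially encoded (0.038), fatty acid oxidation (-0.013), glycolysis (0.021), heat shock (0.025) and Schwann cell (0.023) lists changed direction. Smooth muscle markers passed with the statistics of edgeR (-0.17) and of DESeq2 (-0.17), and the m6A machinery without a filter (0.11) and by camera on ranks (0.089). Among uncalled lists, p53 targets changed direction after median-ratio scaling (0.024), by edgeR (0.021) and by DESeq2 (0.019). Autophagy did so at a mean of at least 5 FPKM (-0.0061), after median-ratio scaling (-0.0067), by edgeR (-0.0066) and DESeq2 (-0.0095), with protein-coding genes (-0.00032), on ranks (-0.00034) and after the length correction (0.0011). Schwann cell markers did so at a mean of at least 5 FPKM (0.033), after median-ratio scaling (0.026), by edgeR (0.032) and DESeq2 (0.029) and after the length correction (0.044), and apoptosis without a filter (0.016).

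With 1 library left out, or without replicate 2 of both groups, oxidative phosphorylation ranged from -0.20 to -0.0073, the first without siNC replicate 3 and the second, in the opposite direction by camera, without replicate 2 of both groups; without siMettl3 replicate 2 alone it was -0.058 and did not pass. The stress response ranged from -0.14 to -0.075 and did not pass without siMettl3 replicate 2 (-0.085) or without replicate 2 of both groups. Uncalled lists ranged from 0.027 to 0.12 (m6A machinery), -0.085 to -0.042 (Toll-like receptor signalling, past the threshold at the lower end), -0.21 to -0.14 (smooth muscle, past it at the lower end), -0.0091 to 0.021 (apoptosis), -0.099 to -0.012 (heat shock), -0.027 to 0.050 (autophagy) and -0.029 to 0.098 (Schwann cell).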

Other observations

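The actin test was set up from genes already seen to fall. The fibroblast-share test, its repeat on fewer markers and the count of exact zeros were chosen after their results were seen. So were the splits for single lists, the standard errors between libraries and the length correction used below. Some terms of lipid metabolism were enriched among the 856 genes that rose by limma; the enrichment was not repeated on the 444 that rose by edgeR, and the fixed fatty acid oxidation list did not pass (adjusted p = 0.539; by edgeR 2 rose and 5 fell). Of 258 genes annotated with lipid metabolic process 35 rose, against 17.6 by chance (Fisher exact test, adjusted p = 0.0499), and of 41 genes of the KEGG pathway of peroxisome proliferator-activated receptors (PPAR), nuclear receptors for fatty acids, 10 did (exact adjusted p = 0.0233). Axon guidance (21 of 138, exact adjusted p = 0.0245) and the synthesis of unsaturated fatty acids (7 of 24, exact adjusted p = 0.0397) were the other KEGG terms on that side. Of the 2621 genes with the longest transcripts 245 rose, against 68 of the 2621 with the shortest. The enrichment was not repeated after the length correction, so terms of long transcripts may be favoured. Among the terms of genes that fell were the cellular response to interferon beta, with 12 of 29 genes, the basement membrane, with 19 of 74, and the KEGG pathway of complement and coagulation, with 10 of 34.

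Cnn1, Acta2, Tagln, Acta1 and Ccn2, which fell, and Ankrd1, which did not pass (-0.37, adjusted p = 0.0526), are known targets of serum response factor and of the coactivator YAP, which respond to the actin cytoskeleton. A hypothesis from this is that a wider set of such genes was lower in siMettl3 cells. In a set of 25 other actin-cytoskeleton and YAP-target genes, written before its values were read, 10 fell and 1 rose, 22 had a fold change below 0 and the median was -0.22. The camera test gave p = 1.28e-11 in the lower direction, p = 0.00611 with an estimated correlation and p = 9.68e-13 after the length correction. These p-values are for 1 set and are not adjusted, unlike those of the fixed lists. With an estimated correlation the matrix list had an unadjusted camera p = 0.00995, and adjusted p = 0.197 over the lists. For the actin set edgeR called 14 lower and 0 higher. The members that fell included Actg2 (-0.80), Ccn1 (-0.55), Myl9 (-0.53), Tpm2 (-0.48) and Filip1l (-0.44), whereas Srf, which encodes serum response factor itself, rose (0.26). The set may therefore have moved together, but smooth muscle cells and fibroblasts also express these genes, and a change in cell shares was not tested for this set.

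The count of called genes and of lists was compared over the 10 ways to divide the 6 libraries into 3 and 3. The real division gave 1432 genes and the highest of the others 6, and 1 of 10 divisions gave as many genes as the real one, itself. For lists, 3 of 10 divisions gave as many as the real one, which called 13, and the highest other called 13. With 10 divisions the share cannot go under 0.1, too few to test chance at 0.05. Each other division also mixes the groups unequally. It keeps part of any group difference, so a real shift of a list could be called there too. The rest of that difference adds to the spread within its sides, which lowers the number of genes called. Neither count therefore tells a real difference from chance. The matrix list was called in 9 other divisions, though with a mean difference of at most 0.23 in size against -0.53. The ribosomal list was called in 8, and the interferon, oxidative phosphorylation, hypertrophy and macrophage lists in 6 each. The cytokine, sarcomere and fibroblast lists were called in 5 each. The NRF2 list was called in 4, the stress response in 3, cholesterol in 1 and the cell cycle in 0. In the other divisions 0 list members were called.

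The ribosomal protein and oxidative phosphorylation lists were lower as lists, with 37 of 38 and 34 of 41 members below 0 and 0 members past the threshold. The libraries differed in their trend with transcript length, with Spearman correlations from -0.38 in siNC replicate 2 to 0.42 in siMettl3 replicate 2, and the genes that rose numbered 68 among the 2621 genes with the shortest transcripts and 245 among the 2621 with the longest. The ribosomal difference from other genes was -0.24, with a standard error of 0.13 between libraries, and that of oxidative phosphorylation -0.14 (0.11). After removal of a trend with transcript length they were -0.168 (0.082) and -0.082 (0.059), both lists stayed past the threshold (camera adjusted p = 3.70e-07 and 0.00462), and 4 and 2 of their members were called lower. Before the correction neither list passed with an estimated correlation (adjusted p = 0.634 and adjusted p = 0.684). Without siMettl3 replicate 2 the ribosomal difference was -0.129 (0.101), without replicate 2 of both groups -0.067 (0.082), and after quantile normalization -0.072. The tests asked for 50% of the ribosomal difference to be kept, which -0.168 and -0.129 exceed by less than their standard errors. A length trend and siMettl3 replicate 2 alone therefore cannot be told apart from a difference between the groups. A spread between libraries in short, abundant transcripts stays open too: 2 of 10 divisions of the libraries gave a ribosomal difference as large, the largest other being 0.255. For oxidative phosphorylation 3 of 10 divisions did, the largest other being 0.182. A lower level of these transcripts through the knockdown was not tested apart from that.

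Some genes had a count of 0 in some libraries and many counts in others. Whether estimates failed or moved in single libraries cannot be told from these counts. They describe the pattern itself and would also arise from real variation between libraries. In all, 87 tested genes had a count of 0 in a library and at least 100 in another of the same group. Over the whole table this held for 83 genes in siNC and 91 in siMettl3, whereas LOC103689951 was the 1 gene with 0 in a whole group and at least 100 in every library of the other. Reads of LOC103689951 given to the overlapping AABR07006049 in siNC are argued against: that gene had a count of 0 in every library, a difference of 0 between the groups. A strain variant is argued against by the design, as all cells came from a single pooled isolate, so both groups would carry it. An induced transcript was not tested.

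The matrix and fibroblast lists fell together with the preset correlation, and neither passed with an estimated one (adjusted p = 0.197 and adjusted p = 0.279). A lower share of fibroblasts is argued against as the whole cause, as long as these markers come mainly from fibroblasts, since it would lower them alike: over 12 markers outside the matrix list the changes differed beyond their errors, from -1.13 (SE 0.068) for Fbln2 to -0.12 (0.055) for Gsn and 0.15 (0.27) for Dpt (log2 with 0.1 FPKM added). Cochran's Q on the limma errors, which is not a permutation test and treats genes as independent, gave p = 2.08e-28 (Q = 159), and p = 0.0148 (Q = 20.6) over the 10 markers other than Fbln2 and Gsn, which carried most of it. A length trend is argued against too, since the matrix difference was -0.574 after its removal and -0.53 before, with standard errors between libraries of 0.043 and 0.031. A smaller change in fibroblast share beneath a change within cells stays open, as does the biological one, a response to the knockdown in either cell type. The labels give cultures, with no count of cell types.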
